A study of Mus musculus with 6 samples.

How the data were processed

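mRNA profiles of 6 mouse livers, 3 taken 4 h after intravenous injection of a lentiviral vector and 3 from untreated mice, were analysed from a table deposited by the authors. RNA was extracted from whole liver and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The genome build mm9 is named in the submitters' processing notes; the aligner, the gene annotation and the counting method are not given in the sources used here.

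The deposited values are treated as a score: whole numbers that the authors appear to have obtained by scaling reads for library size and transcript length and then rounding. No label or header names the unit, and this reading comes from the values. Column sums were nearly alike (497295 to 526009). The variance over the mean among replicates was 0.236 in LV and 0.224 in untreated libraries for genes with a mean of 2 to 5, below the value of 1 that counted reads would give at the least. The first percentile of the mean value was 6.17 in the tenth of genes with the shortest transcripts and 1 in the tenth with the longest, whereas the value multiplied by transcript length in kb gave 7.80 and 9.20; 87.7% of symbols had a length in the reference transcripts. Read depth is therefore unknown, and no interval or detection limit that needs it is given. Rounding removes small differences: a gene at 2 in each LV library and 3 in each untreated library has no measured spread. The table listed 51 genes at 0 in at least 1 library, and 13 row names are numbers, which are not named here.

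Every one of the 6 value columns matched 1 sample by its description. Groups and replicate numbers follow the sample titles. The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The plan assumed read counts with a count model; because the values are a rounded score, the alternative written in the plan for normalized values was used. Genes with a value of at least 1 in at least 3 samples were kept (8386 of 8390). How the 8390 listed genes were chosen is not given in the sources used here. A gene that is absent may therefore be low or left out. log2(value + 1) was fitted by group with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes variance, and p-values are two-sided with Benjamini-Hochberg adjustment over all tested genes. No covariate or block entered the fit.

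Gene lists (39, of which 31 had at least 5 measured members) were written from general knowledge of liver and of the response to viral particles. Of 961 list entries 666 were found in the table, 638 by the listed symbol, 15 by an older symbol and 13 by a unique synonym in a RefSeq gene table of assembly GRCm38.p6, which was used for names and neighbours only; no coordinates are given because the builds differ. Lists were tested with camera in limma (preset correlation 0.01, adjusted over the 31 lists), again with an estimated correlation, and with fry. Counts of list members are given over all genes and adjusted over the list alone. In the interferon-stimulated, class I and retroviral restriction lists the latter equalled the count at an unadjusted p under 0.05. Named genes were the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 whose LV values all lay beyond the untreated ones, up to 4 members with the smallest p from each list, and a fixed set of 37 genes, of which 26 were in the table; some list members were left out of the text for length. Some genes of this rule, and 1 gene list, are not reported here.

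The fit was tested on simulated data for this comparison with 8386 genes and 200 changed genes in each of 5 runs. Of genes changed by a log2 fold of 2, 82% were recovered, of those changed by -2, 70.8%, and of those changed by 1 and -1, 40.4% and 39.2%. False calls made up 13.7% of calls on rounded values, 5.03% without rounding and 4.38% among genes with a mean of at least 5, so counts are also given for the latter. Noise was drawn separately for each gene. Variation shared between genes was therefore not simulated, and these rates may not hold for the real libraries. Alternatives comprised leaving out each library, a replicate block, a pseudocount of 0.1, no filter, quantile normalization and stricter thresholds. After seeing the data, further settings were added: scaling by total, median of ratios or upper quartile, added rounding noise, a mean of at least 5, limma treat against a fold of 1.5, a male-biased gene score as covariate, and leaving out LV replicate 3 and untreated replicate 2 together.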

Results

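Gene expression was measured by RNA sequencing in 6 livers of C57BL/6 mice, an inbred laboratory strain. In the LV group, 3 mice received an intravenous dose of 3e8 transducing units of a lentiviral vector, a replication-deficient particle derived from a retrovirus, and the liver was taken 4 h later. The other 3 mice were untreated. No mock-injected mice are among the 6 samples. Effects of the vector therefore cannot be told apart from those of the injection or handling. The table held 8390 genes with a whole-number value per library, and the values of a library summed to between 497295 and 526009. These sums are not read totals, so the depth of the libraries is unknown and no counting interval is given. Values are quoted in the deposited unit as mean ± SD (n = 3). A fold change is a difference of mean log2(value + 1) between LV and untreated livers and understates the change of genes with low values. Nothing beyond the sample titles describes how the replicates were obtained, so p-values measure the spread between these samples.

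The study asks how the liver responds innately to a lentiviral vector, and the first axis of variation followed that treatment. Pearson correlations of log2 values across genes ranged from 0.942 to 0.981 within the groups and from 0.886 to 0.951 between them, and the ranges overlapped. The first principal component held 58.2% of the variance and placed the 3 LV libraries on one side (-39.5, -27.7 and -13.4) and the 3 untreated libraries on the other (24.4, 28.2 and 28.2). The second component held 24.1% and set LV replicate 3 (-29.5) and untreated replicate 2 (-19.8) apart from the other libraries. In these same libraries the male-biased liver genes were high: Elovl3, a fatty acid elongase, had values of 169 and 159 there and at most 4 in each of the others. Cyp4a12a had 186 and 136 there and at most 3 elsewhere. Cyp2b9, a female-biased P450, had 8 and 5 in these libraries and between 121 and 157 in the others. The Y-linked gene Ddx3y was listed at 0 in untreated replicate 3 and lay between 10 and 14 in the other libraries.

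**Figure D1:**
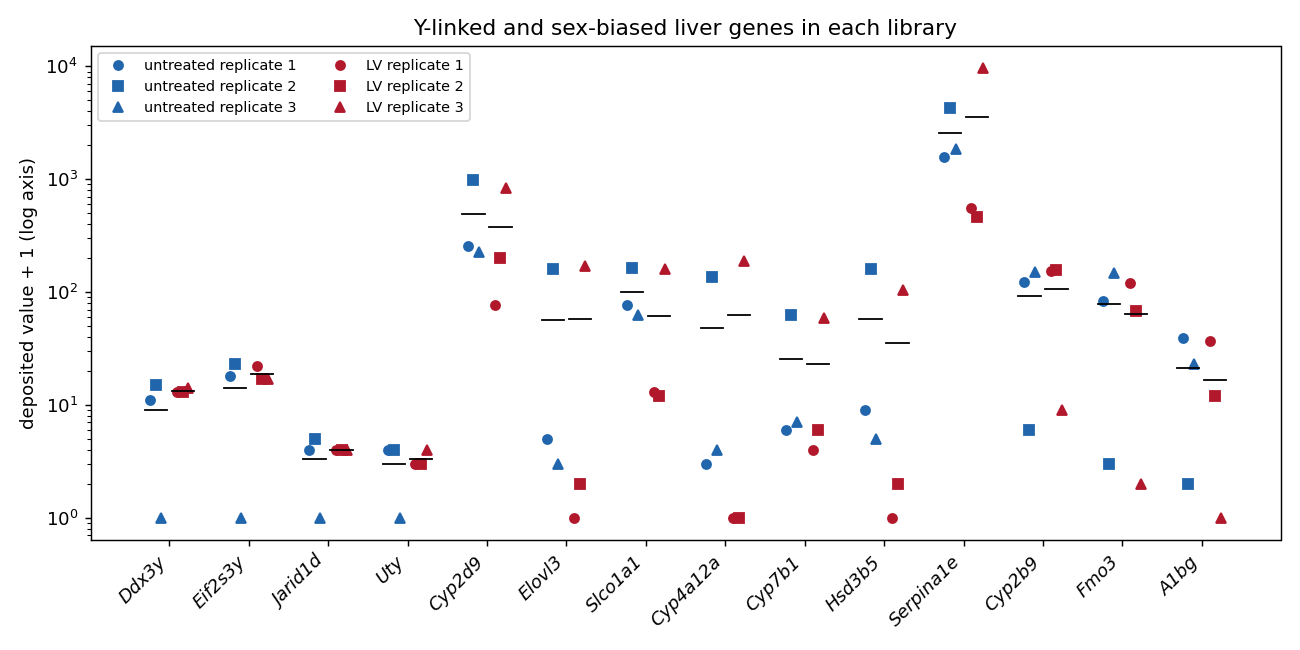
Deposited value + 1 on a log axis for Y-linked genes, male-biased liver genes and 3 female-biased genes in each library, with blue symbols for untreated and red symbols for LV replicates and a bar at each group mean. Elovl3 is high in untreated replicate 2 (159) and LV replicate 3 (169), and the Y-linked genes are listed at 0 in untreated replicate 3.

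Livers taken after the vector showed a broad rise of interferon-response genes. Some acute-phase genes rose too, and few genes fell. Of 8386 genes tested, 315 were higher and 73 lower in LV livers at a Benjamini-Hochberg adjusted p under 0.05 in limma. Large changes went upward: all 118 called genes with a log2 fold change of at least 2 in size were higher, as were all 33 with at least 4. The largest fold change on the log2(value + 1) scale was that of Cxcl10, a chemokine that attracts activated T cells (log2 fold change 6.95 ± 0.31 SE, adjusted p = 0.00134). Ifit1, which binds foreign RNA (6.89 ± 0.34, adjusted p = 0.00139), and Mx1, an interferon-stimulated gene (6.83 ± 0.19, adjusted p = 0.00047), followed. Among the genes that fell, the largest decreases were in Arl4d, a small GTPase (-1.59 ± 0.22, adjusted p = 0.0206), Fads3 (-1.39 ± 0.24, adjusted p = 0.0375) and Glt1d1 (-1.30 ± 0.15, adjusted p = 0.00987). Leaving out LV replicate 1, LV replicate 2, untreated replicate 1 or untreated replicate 3 lowered the total of 388 calls to 186, 130, 192 and 203. Leaving out LV replicate 3 raised the lower genes from 73 to 116. With single libraries left out, the call of Arl4d held only without LV replicate 3, that of Fads3 only without untreated replicate 2, and that of Glt1d1 was lost without LV replicate 1, LV replicate 2 or untreated replicate 3, with adjusted p values of up to 0.102, 0.151 and 0.0609. The deposited values are rounded, and 32 calls (21 of them lower genes) concern genes with no spread in either group. Of all calls, 327 (284 higher and 43 lower) concerned genes with a mean of at least 5.

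**Figure D2:**
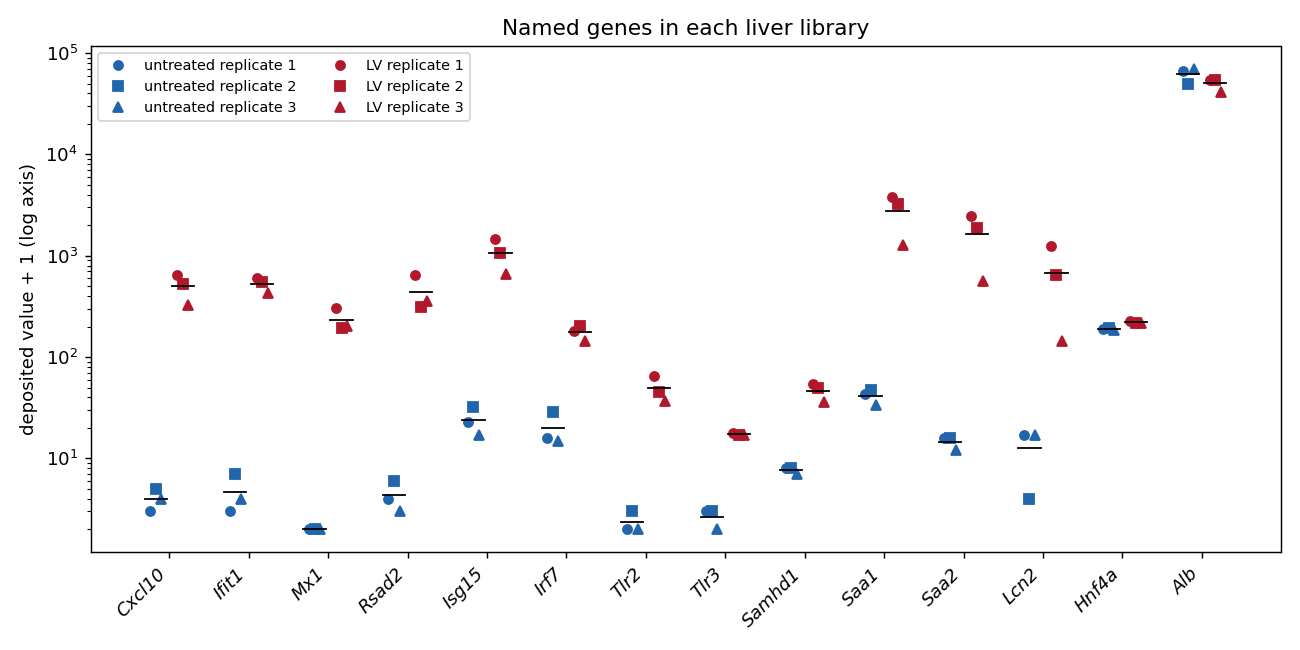
Deposited value + 1 on a log axis for 14 named genes in each library, with blue symbols for untreated and red symbols for LV replicates and a bar at each group mean. All 3 LV values of Cxcl10 (328 to 645) lie above all 3 untreated values (2 to 4), while those of Hnf4a lie between 216 and 227 against 184 to 193.

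Interferon-stimulated antiviral genes rose almost without exception. Of 58 measured members, 55 were higher and 3 did not pass. All 58 were higher when adjusted over the list alone (median log2 fold change 2.57). Rsad2, which blocks viral replication, went from 3.33 ± 1.53 to 438 ± 184, and Isg15, a ubiquitin-like modifier, from 23 ± 7.55 to 1054 ± 400. Irf7, the main amplifier of type I interferon production, rose by a log2 fold change of 3.19 ± 0.29 (limma adjusted p = 0.00486). The list stood apart from other genes in camera (adjusted p = 5.09e-69; adjusted p = 0.139 with an estimated correlation). Guanylate-binding proteins and immunity-related GTPases, which attack intracellular pathogens, followed: 15 of 16 measured members were higher and 16 when adjusted over the list alone, with Igtp at 469 ± 130 against 22.7 ± 5.13 (camera adjusted p = 1.73e-24; adjusted p = 0.139 with an estimated correlation). Ifi47 of this family rose from 10.3 ± 3.06 to 261 ± 65.3. Members of the family are close in sequence, and the split of reads between them is uncertain. Of the 27 listed interferons and receptors, 5 genes were measured, all of them receptor subunits, and 0 passed. No interferon gene of the list was measured, so changes of interferon transcripts could not be assessed. Adjusted over the list alone, and at an unadjusted p under 0.05, 1 was higher, the receptor subunit Ifngr2 (0.60 ± 0.13, limma adjusted p = 0.0767 over all genes, and 0.029 without untreated replicate 3). Ifnb1 was not among the 8390 genes listed.

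Class I antigen presentation genes rose in part. Of 21 measured members, 9 were higher and 12 did not pass, and 15 were higher when adjusted over the list alone (camera adjusted p = 1.43e-11; adjusted p = 0.198 with an estimated correlation). The 9 calls fell to 3 without LV replicate 1, 1 without LV replicate 2, 2 without untreated replicate 1, 3 without untreated replicate 2 and 2 without untreated replicate 3. The members that rose included Tap1, the peptide transporter (from 13.7 ± 0.577 to 95 ± 19.98), and Psmb9, an immunoproteasome subunit (log2 fold change 2.17 ± 0.23, limma adjusted p = 0.00867, but 0.0606 without LV replicate 2 and 0.0557 without untreated replicate 3). H2-K1 had a log2 fold change of 0.28 and B2m, the light chain of class I molecules, of 0.08 (adjusted p = 0.194 and 0.853). Of 5 measured class II genes, 0 passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Cd74, the invariant chain, was 59.3 ± 26.5 in LV and 74 ± 18.2 in untreated livers.

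Several sensors of microbial and viral molecules rose. Among Toll-like receptors and their adaptors, 4 of 16 measured genes were higher and 12 did not pass. The 4 calls fell to 2 when LV replicate 2, untreated replicate 2 or untreated replicate 3 was left out. Adjusted over the list alone, 4 were higher and 2 lower. Tlr2, a receptor for lipoproteins, went from 1.33 ± 0.577 to 48 ± 14.4, and Tlr3, the receptor for double-stranded RNA, from 1.67 ± 0.577 to 16.3 ± 0.577. Myd88, the adaptor of most Toll-like receptors, rose by a log2 fold change of 1.88 ± 0.25 (limma adjusted p = 0.0159), with adjusted p between 0.0686 and 0.095 when LV replicate 2 or any 1 of the 3 untreated libraries was left out. Tlr4, Tlr7 and Tlr9 were not among the 8390 genes listed. In camera the list had an adjusted p = 0.0133 (adjusted p = 0.47 with an estimated correlation), and 0.0656 without LV replicate 3 and untreated replicate 2, a setting chosen after seeing the data. Cytosolic nucleic acid sensors gave 10 higher of 14 measured genes, and 11 higher when adjusted over the list alone (camera adjusted p = 3.63e-13; adjusted p = 0.139 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acid, rose from 7.67 ± 0.577 to 225 ± 56.9, and Trex1, a DNA exonuclease that limits DNA sensing, from 12 ± 1 to 90 ± 8.89. Of the called sensors, Ddx58, Ifih1, Dhx58, Ifi204, Zbp1, Eif2ak2 and Trim25 also belong to the interferon list. Zbp1 is counted again among cell death genes and Trex1 among negative regulators, so the lists are not independent.

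Inflammatory and acute-phase genes also rose in part. Of 7 measured chemokines, 4 were higher and 5 when adjusted over the list alone (camera adjusted p = 1.89e-07; adjusted p = 0.139 with an estimated correlation). Ccl2, which attracts monocytes, was listed at 0 in each untreated library and had 30, 23 and 14 in the LV libraries. Cxcl9 rose by a log2 fold change of 3.40 ± 0.33 (limma adjusted p = 0.00581, and 0.0524 without LV replicate 2). Among inflammatory cytokines and NF-kB targets, 11 of 17 measured genes were higher, and 13 were higher when adjusted over the list alone (camera adjusted p = 4.79e-14; adjusted p = 0.139 with an estimated correlation). The 11 calls fell to 4 without LV replicate 1, 4 without LV replicate 2, 7 without untreated replicate 1 and 5 without untreated replicate 3. They included Csf1, a macrophage growth factor (from 3.67 ± 0.577 to 26 ± 1), and Icam1, a leukocyte adhesion molecule (from 7.33 ± 1.15 to 43.3 ± 9.87). Tnf, Il6, Il1b and Ccl5 were not among the 8390 genes listed, so their levels are unknown. Of 32 measured acute-phase genes, 16 were higher and 16 did not pass. Leaving out LV replicate 1 gave 8 higher acute-phase genes, LV replicate 2 gave 5, untreated replicate 1 gave 5, untreated replicate 2 gave 8 and untreated replicate 3 gave 6. Adjusted over the list alone, 26 were higher and 1 lower (camera adjusted p = 5.28e-22; adjusted p = 0.152 with an estimated correlation). Serum amyloid A genes led: Saa2 had a log2 fold change of 6.57 ± 0.58 (limma adjusted p = 0.00412) and Saa1 of 5.94 ± 0.45 (adjusted p = 0.00248), though these close paralogs can share reads. LV replicate 3 had the smallest of the LV values, with 1264 for Saa1 against 3839 and 3274. It had 144 for Lcn2, an iron-scavenging lipocalin, against 1257 and 646. The adjusted p of Lcn2 was 0.0441, and between 0.113 and 0.176 when LV replicate 1, LV replicate 2 or any 1 of the untreated libraries was left out.

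Most measured members of the list written for retroviral restriction factors rose. Whether each member restricts retroviruses in mice was not tested. Of 24 measured members, 19 were higher and 5 did not pass, and 22 were higher when adjusted over the list alone (camera adjusted p = 2.49e-27; adjusted p = 0.139 with an estimated correlation). Without LV replicate 1, and likewise without LV replicate 2, 12 of them were called. Samhd1, which depletes the nucleotides needed for reverse transcription, went from 6.67 ± 0.577 to 45.7 ± 9.45, and Trim30 from 2.33 ± 0.577 to 27 ± 4. Bst2, which tethers budding virions, was already at 188 ± 27.8 and reached 387 ± 70.7 (limma adjusted p = 0.0468), with adjusted p between 0.113 and 0.18 when LV replicate 1, LV replicate 2 or any 1 of the untreated libraries was left out. Many of these genes also belong to the interferon list. Negative regulators of cytokine signalling gave 6 higher of 16 measured genes, and 9 higher when adjusted over the list alone (camera adjusted p = 1.24e-07; adjusted p = 0.139 with an estimated correlation). Cd274, the ligand of an inhibitory receptor of T cells, had 37, 29 and 31 in LV and 1, 1 and 0 in untreated libraries (adjusted p = 0.00189, and 0.0545 without LV replicate 3 and untreated replicate 2). Usp18, which removes Isg15 from proteins, went from 14 ± 3 to 271 ± 64.1. Both Usp18 and Isg15, called in this list, also belong to the interferon list. Socs3 had a log2 fold change of 1.47 ± 0.36 (adjusted p = 0.0965). Cell death genes gave 6 higher of 20, and 14 higher when adjusted over the list alone, among them Mlkl, the effector of necroptosis (2.70 ± 0.21, adjusted p = 0.00264; camera adjusted p = 5.36e-09 for the list; adjusted p = 0.199 with an estimated correlation).

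**Figure D3:**
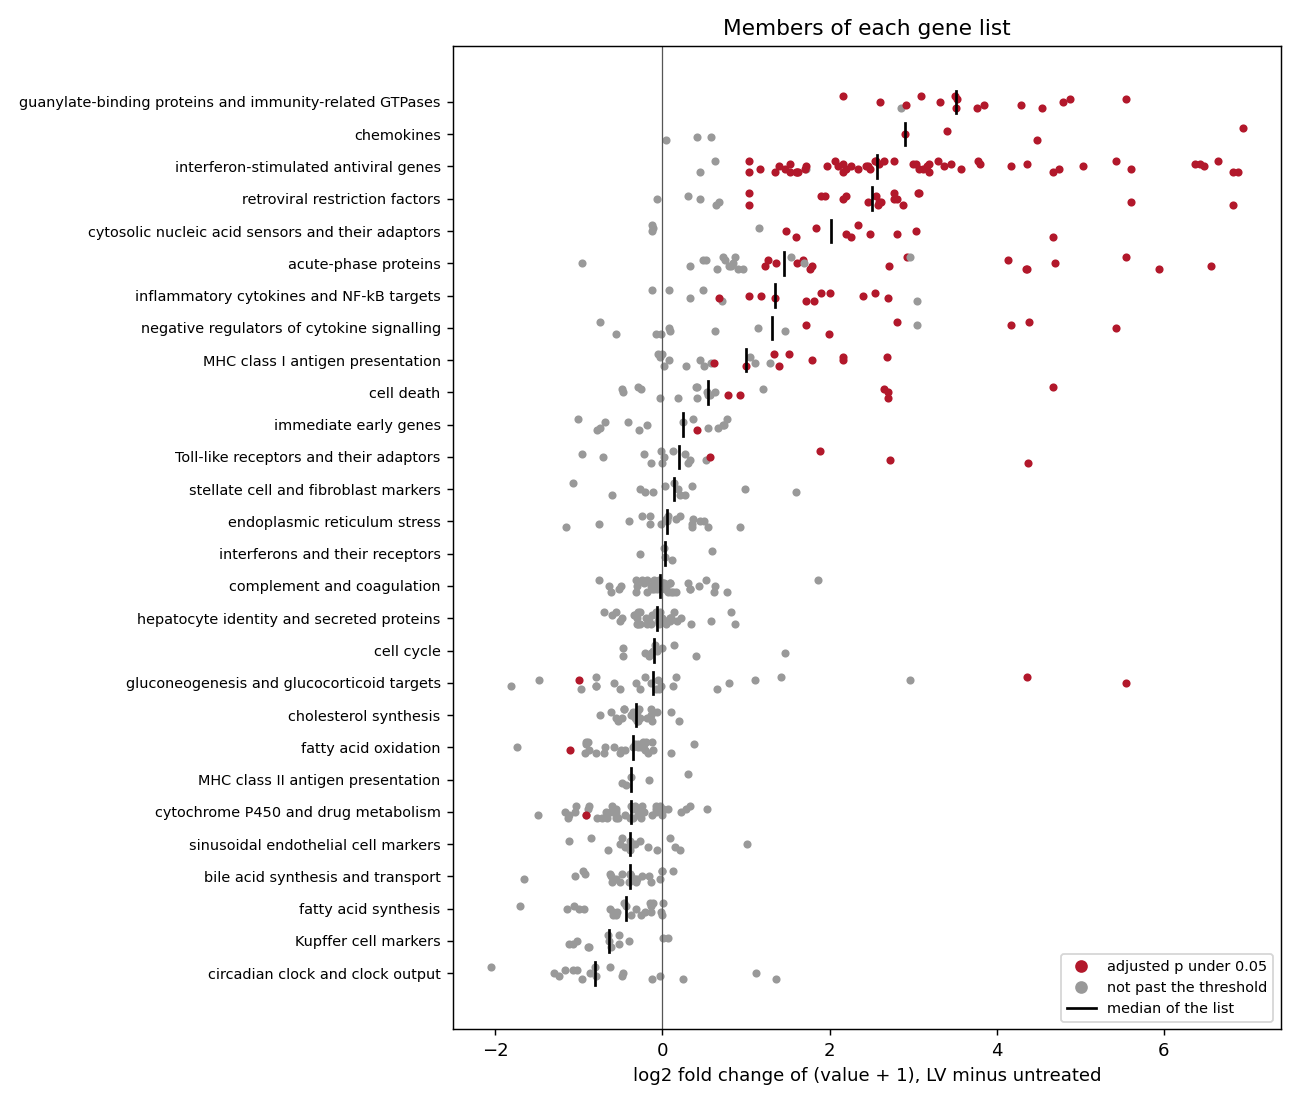
Log2 fold change of (value + 1), LV minus untreated, for each measured member of the gene lists with at least 5 measured genes that are reported here, apart from the sex-specific lists, sorted by the list median (black bar); red points have an adjusted p under 0.05 and grey points do not. The interferon-stimulated list has 55 red points of 58 and a median of 2.57, and the fatty acid oxidation list 1 of 29 and a median of -0.35.

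Hepatocyte genes showed no call in the identity list, and metabolic lists lay below 0 to a degree that differed between the LV libraries. The median log2 fold change of all tested genes was -0.07, so negative fold changes were common beyond these lists. They made up 33 of 37 complex I subunits, 35 of 48 cytosolic and 51 of 70 mitochondrial ribosomal proteins. Of proteasome subunits 17 of 37 were negative, and of ubiquitin-specific proteases 15 of 35. Of 42 measured genes of hepatocyte identity and secreted proteins, 0 passed in limma, over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05 (3 higher, 3 lower; camera adjusted p = 0.851). Without LV replicate 3, 1 was higher and 2 were lower. Albumin (Alb) was 50232 ± 7389 in LV and 61581 ± 11042 in untreated livers (adjusted p = 0.587). Hnf4a, a master regulator of hepatocytes, had a log2 fold change of 0.22 ± 0.07 (adjusted p = 0.16). Of 29 measured fatty acid oxidation genes, 27 had a negative fold change and 1 passed, Acaa1b, a peroxisomal thiolase (-1.10 ± 0.20, limma adjusted p = 0.0443); 3 were lower without untreated replicate 2. Adjusted over the list alone, 0 passed. The list was lower in camera (adjusted p = 0.000112, and 0.491 with an estimated correlation) but was not called by fry (adjusted p = 0.0902). Of 48 genes of P450 and drug metabolism, 42 had a negative fold change and 1 passed, a carboxylesterase listed as Ces3 (-0.92 ± 0.13, adjusted p = 0.0234), also when adjusted over the list alone (camera adjusted p = 0.00548; adjusted p = 0.383 with an estimated correlation). With single libraries left out, the call of Acaa1b held only without untreated replicate 2 and that of Ces3 only without untreated replicate 1. Leaving out any other library gave adjusted p values of up to 0.16 and 0.117. Cyp3a11, a main drug-metabolising P450, was 1014 ± 57.5 against 1233 ± 259 (adjusted p = 0.439). Bile acid genes gave 23 of 24 negative fold changes, 0 calls over all genes or adjusted over the list alone and 6 lower genes at an unadjusted p under 0.05 (camera adjusted p = 0.00268; adjusted p = 0.386 with an estimated correlation). The medians per library, relative to the untreated mean, were -0.64, -0.42 and -0.15 in LV replicates 1, 2 and 3 for P450 and drug metabolism and -0.74, -0.38 and -0.14 for bile acid genes. The lowest untreated medians were -0.14 and -0.12, so LV replicate 3 lay near the lowest untreated library for these lists. For fatty acid oxidation it did not. There the medians were -0.45, -0.26 and -0.41 in LV replicates 1, 2 and 3, and the lowest untreated one was -0.21. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 22, 32 and 12 in LV and 17, 48 and 25 in untreated livers (adjusted p = 0.687). Fatty acid synthesis genes gave 21 of 23 negative fold changes and 0 calls by either adjustment, with 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00548; adjusted p = 0.47 with an estimated correlation). The median of this list was -0.36, -0.30 and -0.47 in LV replicates 1, 2 and 3. It was -0.34 in untreated replicate 3, below that of LV replicate 2. This list had an adjusted p of 0.0679 without LV replicate 3 and 0.104 without LV replicate 3 and untreated replicate 2, the libraries with high male-biased genes. Some genes of these metabolic lists also belong to the sex-specific lists. They include Cyp2d9, Cyp4a12a, Cyp2b9, Cyp2b13, Cyp2a4 and Cyp3a41a (P450), Slco1a1 and Cyp7b1 (bile acids), Elovl3 (fatty acid synthesis) and Acot3 (fatty acid oxidation). Several of them differed between libraries of the same group, and their part in the list medians was not tested. Of 24 cholesterol synthesis genes 0 passed by either adjustment and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.257; 0.00979 without untreated replicate 2, 0.0318 without LV replicate 1 and 0.0325 without LV replicate 2). Of 26 genes of gluconeogenesis and glucocorticoid action, 2 were higher (Lcn2 and Mt2) and 1 lower, Tsc22d3, a glucocorticoid-induced regulator (-0.996 ± 0.16, adjusted p = 0.0303). Adjusted over the list alone, 3 were higher and 2 lower (camera adjusted p = 0.993). Their calls (adjusted p = 0.0362 for Mt2), with single libraries left out, held for Tsc22d3 and Mt2 only without LV replicate 3. Leaving out any other library gave adjusted p values of up to 0.123 and 0.158. The list had 0 calls without LV replicate 1, untreated replicate 1 or untreated replicate 2, 1 lower gene without LV replicate 2, and 2 higher and 0 lower genes without untreated replicate 3.

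Markers of other liver cells gave few calls. Of 13 measured Kupffer cell markers, which label the resident macrophages, 11 had a negative fold change and 0 passed, over all genes or adjusted over the list alone, with 3 lower at an unadjusted p under 0.05. Vsig4 was 7.33 ± 2.52 in LV and 16.7 ± 1.53 in untreated livers (limma adjusted p = 0.0693). The list was lower in camera (adjusted p = 0.00729; adjusted p = 0.604 with an estimated correlation) but not without LV replicate 1 (0.0529), LV replicate 3 (0.0517) or untreated replicate 3 (0.0842). Its median per library, relative to the untreated mean, was -1.11 in LV replicate 1, -0.08 in LV replicate 2 and -0.64 in LV replicate 3. Of 17 sinusoidal endothelial markers 0 passed by either adjustment (1 higher and 1 lower at an unadjusted p under 0.05). Fold changes were negative for 13 and positive for 4 of them. Clec4g had 11, 43 and 33 in the LV libraries against 54 to 58 in the untreated ones (limma adjusted p = 0.29). Lyve1 went the other way, with a log2 fold change of 1.015 (limma adjusted p = 0.131). For the list camera gave an adjusted p of 0.26, and of 0.0343 without LV replicate 2. Of 3 measured monocyte markers, Plac8 was higher (1.94 ± 0.30, adjusted p = 0.0287), and 2 were higher when adjusted over the list alone. Among the leave-outs, the call of Plac8 held only without LV replicate 3, with adjusted p values of up to 0.125 when any other library was left out. Of 13 stellate cell and fibroblast markers 0 passed, 2 were lower when adjusted over the list alone, and 2 were higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.851). Without LV replicate 1, and likewise without LV replicate 3, 1 of them was lower. Neutrophil, T cell and NK cell markers had 0 measured members, so these cells could not be assessed. Markers of B cells (1 measured), cholangiocytes (3), erythroid cells and platelets (3) and pancreas (1) gave 0 calls. The B cell gene, Fcrla, was lower when adjusted over the list alone, but with 1 gene this adjustment changes nothing (limma adjusted p = 0.193 over all genes). Of 2 dendritic cell markers, 1 passed, Bst2 of the restriction factors. Female-specific genes gave 0 calls of 10 and male-specific genes 0 of 11 by either adjustment (camera adjusted p = 0.439 and 0.851). Circadian clock genes gave 0 calls among 18 by either adjustment, with 2 higher and 8 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0332; adjusted p = 0.618 with an estimated correlation). The circadian list did not pass without LV replicate 1 (0.094), LV replicate 3 (0.0965), untreated replicate 2 (0.0814) or untreated replicate 3 (0.233). Immediate early genes gave 1 call of 15, and 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.26). The call was Fosl2, with 3 in each LV and 2 in each untreated library; it has no spread and was lost with added rounding noise (adjusted p = 0.321) and without LV replicate 2 (0.0524). The list had 0 calls without LV replicate 2, 2 higher without LV replicate 3, and 1 higher and 1 lower without untreated replicate 2. Genes of endoplasmic reticulum stress (20), cell cycle (12) and complement and coagulation (41) gave 0 calls by either adjustment, with 4, 1 and 7 genes at an unadjusted p under 0.05 (camera adjusted p = 0.413, 0.75 and 0.383). The cell cycle and complement lists had a median below and a mean above 0, as did gluconeogenesis, and the male-specific list had a median and mean below 0 while camera placed it upward.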

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

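Settings chosen after seeing the data are the scalings by total, median of ratios and upper quartile, the rounding noise, the mean filter, treat, the male-biased covariate and the joint removal of LV replicate 3 and untreated replicate 2, with quantile normalization for lists and named genes; the others were planned. No called named gene changed direction in any setting, and of 66 called named genes 36 passed in all 18 settings. Leaving out 1 library gave between 130 and 433 genes (120 to 317 higher, 10 to 116 lower), against 388 (315 and 73); fewer samples are tested there. The replicate block gave 156 (145 higher, 11 lower). Same-numbered libraries had deviation correlations of 0.28, -0.47 and -0.34, and not every library correlated best with its own number. These values give no sign of pairing by number but cannot exclude it with so few libraries per group. An adjusted p under 0.01 left 175 (156 and 19), a log2 fold change of at least 1 left 256 with 10 lower, and treat against a fold of 1.5 left 136 (136 and 0, with 357 at an unadjusted p under 0.05). Without LV replicate 3 and untreated replicate 2 together, 314 genes were higher, of which 184 were shared with the 315. In the same setting 138 genes were lower, of which 29 were shared with the 73. The cause was not tested. Camera called 17 lists (11 higher, 6 lower) and 0 with an estimated correlation (8 at an unadjusted p under 0.05). By fry 11 were higher and 2 lower, P450 and drug metabolism (adjusted p = 0.0497) and bile acid genes (0.0404). It did not call fatty acid oxidation (0.0902), fatty acid synthesis (0.118), Kupffer cell markers (0.259) or the circadian list (0.212). With the male-biased covariate camera placed 3 lists lower, cell cycle (adjusted p = 0.0473), female-specific genes (0.0163) and cholesterol synthesis (3.53e-06), where the fit without it called 0 of them (0.75, 0.439 and 0.257); the cause was not tested. Other settings kept the total of called genes within 1.5 times. By list, the replicate block gave 2 class I genes (9 without it), 2 Toll-like receptor genes (4) and 5 acute-phase genes (16). The joint removal gave 5 class I, 2 Toll-like receptor, 5 NF-kB (11), 9 acute-phase and 3 negative-regulator genes (6), and the covariate 7 NF-kB genes. Lists with at most 3 calls changed by at most 2 per direction. The planned tests with edgeR, DESeq2 and voom, with their normalization factors, and those on recovered reads were not run, since the values are not counts; a minimum of 1 per sample in 3 samples equals the filter used. Unknown depth and rounding limit genes with low values.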

Other observations

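Outside the fixed lists, 180 further genes were higher in LV livers. Irf1, a factor downstream of interferon and NF-kB, had a log2 fold change of 2.18 (limma adjusted p = 0.00178), and Parp11 of 2.48 (adjusted p = 0.00189). Hmox1, haem oxygenase, had 2.03 (adjusted p = 0.00364), and Slc39a14, a zinc and iron importer, 1.55 (adjusted p = 0.00987, and up to 0.0664 without LV replicate 1, LV replicate 2, untreated replicate 1 or untreated replicate 3). Id3, an inhibitor of helix-loop-helix factors, had 1.49 (adjusted p = 0.00144). These genes were chosen after their values were seen. Cytosolic ribosomal proteins gave 0 higher and 0 lower genes of 48, mitochondrial ones 0 and 0 of 70, in limma, with 4 and 6 genes at an unadjusted p under 0.05. The olfactory receptor gene Olfr56 had values of 215, 264 and 95 against 4, 5 and 3; it neighbours Ifi47 in the reference annotation, and reads of both were not separated here.

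The tests on the sex-related and acute-phase patterns below were chosen only after the result was seen, and the rounding noise was added as a setting after seeing the data. The split of the 6 libraries into LV and untreated gave 388 genes, and the highest of the other splits gave 5. Since the real split is itself 1 of the 10, the share cannot fall under the threshold, and nothing more can be said. Rounding was weighed for the called genes. Of the 32 called genes with no spread in either group, 3.13% kept a median adjusted p under 0.05 over 20 draws of added rounding noise, so these calls may come from rounding. Of the 356 with spread, 93.3% kept it. Over all calls, with or without spread, 296 of the 315 higher and 37 of the 73 lower ones were kept. This argues against rounding as the source of the higher calls with spread. For the lower calls rounding stays open.

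Male-biased liver genes were low in 4 of the 6 libraries and high in LV replicate 3 and untreated replicate 2. Female animals are argued against for LV replicates 1 and 2 and untreated replicate 1, since in all 3 of these libraries the 4 Y-linked genes were above 0. In untreated replicate 3, 0 of 4 Y-linked genes were above 0, and a female animal may account for that library. For the others the age, housing or hormonal state of the animals stays open; the labels used here give neither sex nor age. The pattern crosses the treatment groups, but among the libraries with low values the LV ones lay lower. The mean log2 value of the male-biased genes was 3.01 and 3.53 in LV replicates 1 and 2. In untreated replicates 1 and 3 it was 4.93 and 4.77. A comparison of growth genes between the libraries with low and high male-biased genes was made after seeing the data and dropped, because it grouped livers by a measured outcome; its values are not used here.

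The acute-phase rise was smaller in LV replicate 3, where 29 of 32 genes lay below the mean of the other LV libraries (median -0.53 on the log2 scale); interferon-stimulated genes were also lower there (53 of 58, median -0.29). The scale of the whole library is argued against, since the median over all genes was 0. A baseline difference of livers with high male-biased genes cannot be told apart from a difference in response: in untreated replicate 2 the acute-phase median against the other untreated libraries was -0.0887, between 0 and the value in LV replicate 3, and 1 library per group leaves it open. Not every induced list was lower in LV replicate 3: the median log2 change of inflammatory cytokines and NF-kB targets against the untreated mean was 1.43 there against 1.35 and 1.38 in LV replicates 1 and 2, and that of negative regulators 1.45 against 1.42 and 1.09.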
